A study of Homo sapiens with 3 samples.

How the data were processed

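Gene expression was measured by RNA sequencing in 3 libraries labelled HCT116, 1 each for the empty vector, wild-type ZEB1 and ZEB1 K80R overexpression groups, which were taken from the genotype given in the labels. Per the labels' protocols, total RNA was extracted with RNAiso Plus and libraries were made with a SMARTER mRNA sequencing kit. The submitters' processing notes name CASAVA, featureCounts 1.5.0-p3, DESeq2 1.20.0 and the genome build hg38, without giving their roles or order. The aligner, the strand setting and the annotation were not given in the sources used here. The authors deposited 1 table of FPKM values, fragments scaled by gene length and library size, with gene identifiers, names, biotypes, lengths and coordinates for 58735 genes, and no other per-sample columns. All 58735 identifiers were found in GENCODE release 29 (Ensembl 94, GRCh38), so the coordinates in the table are given as GRCh38.

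The deposited FPKM values kept the read counts. In each library the product of FPKM and gene length was a whole multiple of a single step for 100.0% of the genes above 0, within a tolerance of 0.05 reads, which gave the reads of each gene. The reads summed to 14764535, 14322537 and 13479517 in the empty vector, wild-type ZEB1 and ZEB1 K80R libraries, while the step corresponded to library sizes of 15886593, 13795840 and 13321338. The FPKM therefore hold a library factor of 1.076, 0.963 and 0.988 relative to the read sums, whose origin is not given in the sources used here. Such a factor moves all genes of a library alike. The recovered reads served for the counting intervals only, which are exact conditional (Clopper-Pearson) 95% intervals of the ratio of FPKM of a gene between a pair of libraries. They cover counting error only, since reads copied from the same molecule are not independent. A gene with 0 reads may have up to 3 reads by counting error. FPKM depends on gene length and on the composition of each library, so a library in which a few genes take many reads can have lower values for all others. The shares of reads on mitochondrial genes were 1.29%, 7.77% and 9.75%. In the deposited values the median gene still differed little on the log2 scale. It differed by 0.011 for wild type and 0.005 for K80R against empty vector, and by −0.018 for K80R against wild type.

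With 1 library per group there was no test of the conditions and no p-value. The FPKM table was the unit foreseen in the design, so the design was kept. The difference of a gene between a pair of libraries was taken as the difference of log2(FPKM + 1), a scale with a pseudocount of 1 that understates the differences of low genes, while ratios in the text are of FPKM without a pseudocount. Genes with a mean FPKM over the 3 libraries of at least 1 were compared, 12605 in all and 10372 protein-coding with a symbol. A gene high in a single library can pass this filter through that library alone, which tilts counts of list members towards it. Over all genes a ratio of FPKM + 1 of at least 2 was counted, and within gene lists a ratio of at least 1.5. The median of each list was set against 10000 random lists of the same size drawn from the 10372 protein-coding genes and matched on mean expression in 20 bins. A median outside the central 95% of them describes these libraries and is no test of the conditions. Lists needed at least 5 measured members.

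The 3 comparisons, the 22 gene lists, the rule for named genes and the first set of alternative settings were fixed before the data were examined. The lists were NF-κB components and feedback genes, pro-inflammatory cytokines and chemokines, mesenchymal genes, epithelial junction and identity genes, type I interferon response, MHC class I antigen presentation, TGF-β response, Wnt targets, matrix proteases and invasion genes, p53 targets, cell cycle and mitosis, unfolded protein and integrated stress response, hypoxia and glycolysis, immediate early and AP-1 genes, cholesterol synthesis, metallothioneins and oxidative stress, heat shock, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, replication-dependent histones, markers of cells other than colon epithelium, and housekeeping genes. Named genes were ZEB1, CDH1 and VIM, the 8 protein-coding genes with the largest difference in each direction of each comparison, up to 4 members with the largest difference from each list described, and, for K80R against wild type, each member of the first 2 lists that differed by at least 1.5-fold. This rule gave 59, 55 and 95 genes for the 3 comparisons, of which the text names a part. Further genes named as list members within range, as shared between comparisons or as colon epithelial, intestinal, respiratory chain or replication genes were chosen after their values were seen. Y-linked genes and XIST were left out of all gene tables. Another 4 lists were added after the data were seen, namely colon epithelial genes, intestinal epithelial genes, nuclear-encoded respiratory chain subunits, and DNA replication and damage response genes.

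This set held a pseudocount of 0.1, no filter or other filters on low values, FPKM rescaled to a common sum in every library (TPM) or by the median ratio between libraries, protein-coding genes alone, a ratio of 1.5 and the mean in place of the median of a list. Alternatives chosen after seeing the data were a correction of the differences for the length and GC content of the longest annotated transcript by a quadratic fit, a filter without the empty vector library, the common sum for the medians of lists, and a count of only those genes whose counting interval excludes 1. The overlap of both comparisons against the single empty vector library was set beside independent lists and beside 100 simulations of unchanged libraries.

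The steps were tested on simulated data, a pair of libraries with the read counts of the wild-type ZEB1 library and 10325 measured genes. All simulated reads were recovered. Of 50 genes simulated 4-fold higher 100.0% passed a ratio of 2, of 45 simulated at 0.25 88.9% did, and of 50 simulated 2-fold higher 14.0% passed a ratio of 2 and 98.0% a ratio of 1.5, so a count at a ratio of 2 misses most genes simulated 2-fold higher. Of 46 genes simulated at 0.5, 2.2% passed a ratio of 2 and 89.1% a ratio of 1.5. Of 10134 unchanged genes, 0 passed a ratio of 2 and 7 a ratio of 1.5. Of 100 unshifted lists of 20 genes 6 fell outside the central 95%, and of 100 lists shifted by 0.3 all did. These simulations hold counting error only. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.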

Results

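RNA sequencing compared 3 libraries from cultures labelled HCT116, a human colorectal carcinoma cell line, with 1 library in each of 3 groups. The groups were an empty vector control, cells made to overexpress wild-type ZEB1, and cells made to overexpress ZEB1 K80R, a form in which a lysine is replaced by an arginine. ZEB1 is a zinc-finger transcription factor that represses epithelial genes such as CDH1 and promotes epithelial-mesenchymal transition (EMT). The title of the series poses the question of these comparisons: how the K80R form bears on NF-κB signalling, on EMT and on the genes of inflammation. The deposited values were FPKM of 58735 genes, and the reads behind them came to 14764535 for the empty vector library, 14322537 for the wild-type ZEB1 library and 13479517 for the ZEB1 K80R library. No group had a replicate, so no difference could be set against a spread between cultures, and every comparison is one of single libraries. Intervals in brackets are exact 95% counting intervals of a ratio of FPKM, which cover counting error only. A count of 3 reads, taken as the limit that a count of 0 allows, was worth an FPKM of 0.094, 0.109 and 0.113 for a gene of 2 kb in the empty vector, wild-type ZEB1 and ZEB1 K80R libraries.

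ZEB1 itself was higher in both overexpression libraries than in the empty vector library. ZEB1 (ENSG00000148516; GRCh38, chromosome 10, 31318495 to 31529814, plus strand) had an FPKM of 5.66 from 778 reads in the empty vector library, 9.83 from 1173 reads in the wild-type ZEB1 library and 10.3 from 1188 reads in the ZEB1 K80R library. The ratio to empty vector was 1.74 (1.58 to 1.90) for wild-type ZEB1 and 1.82 (1.66 to 2.0) for ZEB1 K80R, and the ratio of K80R to wild type was 1.05 (0.97 to 1.14). Rescaled to a common sum of FPKM (TPM), the levels were 25.3, 32.0 and 33.9 in the same order, a smaller distance from empty vector. As ratios of FPKM + 1 to empty vector, ZEB1 stood at 1.63 for wild type and 1.7 for K80R. By that measure 1786 and 1592 of 12605 genes were at least 1.5-fold higher than in the empty vector library, so the rise of ZEB1 did not stand out. The values are per gene, so reads of the introduced and of the endogenous ZEB1 were not told apart, and the table does not show which overexpression library carries the K80R form. CDH1, the E-cadherin gene that ZEB1 represses (ENSG00000039068; chromosome 16, 68737225 to 68835548), had 0 reads in all 3 libraries, the empty vector library included. VIM, which encodes the mesenchymal intermediate filament vimentin (ENSG00000026025; chromosome 10, 17228259 to 17237593), had an FPKM of 282.7 in the empty vector library, 545.8 in the wild-type ZEB1 library and 435.6 in the ZEB1 K80R library.

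The libraries labelled HCT116 had few or no reads on genes typical of colon epithelium. A set of 19 such genes, chosen after their values had been seen, held 11 with 0 reads in all 3 libraries, among them EPCAM (chromosome 2, 47345158 to 47387601), the intestinal transcription factors CDX1, CDX2 and HNF4A, the brush border gene VIL1 and the adhesion genes CEACAM5 and CEACAM6. None of the 19 reached an FPKM of 1 in any library, and the highest was the mucin gene MUC13, with 13 reads and an FPKM of 0.28. Of the 45 epithelial junction and identity genes, 10 had 0 reads throughout and 8 reached a mean FPKM of 1, among them the keratins KRT8, at 41.3, 49.5 and 41.6 in empty vector, wild type and K80R, and KRT18, at 51.5, 51.7 and 48.0. Of the 36 mesenchymal genes, 31 reached a mean FPKM of 1. Of 22 marker genes of other cells, such as leukocytes, endothelium and hepatocytes, 8 had 0 reads throughout and only the neurofilament gene NEFL and the receptor gene PDGFRB reached a mean FPKM of 1. NEFL stood at 71.9, 45.0 and 50.03, and PDGFRB at 0.573, 2.19 and 1.54. All 66 housekeeping and ribosomal protein genes had reads in every library.

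**Figure D1:**
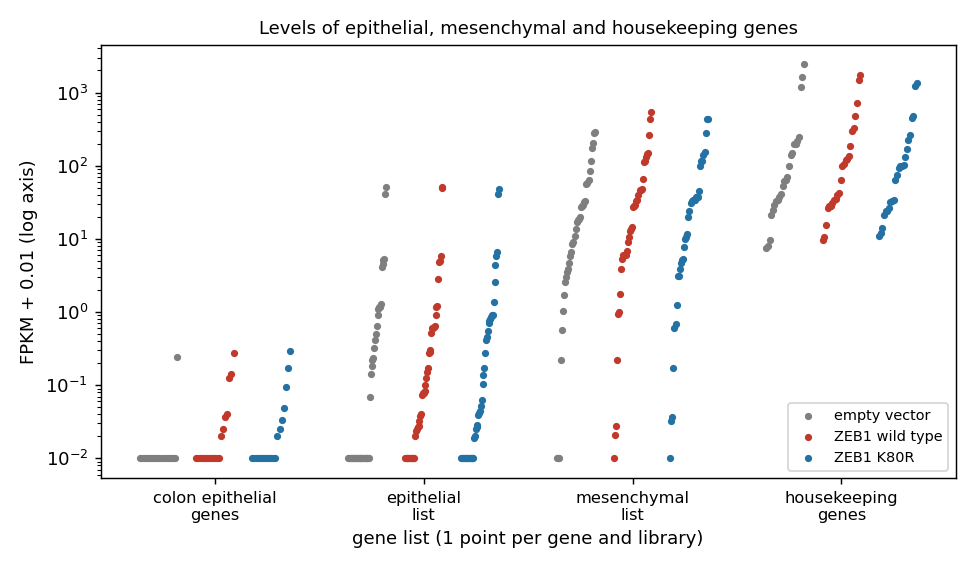
FPKM + 0.01 on a log axis of each gene of 4 lists, with 1 point per gene and library in grey for empty vector, red for wild-type ZEB1 and blue for ZEB1 K80R. The 19 colon epithelial genes, chosen after their values had been seen, lie at or below an FPKM of 0.28 in all 3 libraries, while mesenchymal genes reach 545.8.

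The empty vector library also differed from the other libraries in how its reads were spread over genes. It had reads on 18928 genes, against 23457 in the wild-type ZEB1 library and 24325 in the ZEB1 K80R library. It held 350 genes with exactly 1 read and 404 with 5 reads, where the wild-type library held 2705 and 627 and the K80R library 2902 and 658. Mitochondrial genes took 1.29% of its reads, 7.77% of those of the wild-type library and 9.75% of those of the K80R library. The sum of FPKM over genes was 223875, 307544 and 303683 in the same order. Mitochondrially encoded mRNAs held most of the excess of the overexpression libraries in that sum. MT-CO1 stood at 1788, 12217 and 13172 FPKM, MT-ATP6 at 736, 10658 and 12878 and MT-CO2 at 913, 10986 and 12282. A rescaling to a common sum shifted the median gene by −0.45 on the log2 scale for wild type and by −0.43 for K80R against empty vector. For K80R against wild type the shift was 0.02. A rescaling by the median ratio shifted it by only −0.01, 0.01 and 0.02 in these comparisons, so the deposited values already lay near that scale. Because these scalings differ, the differences from empty vector given here are relative to the other genes of the same libraries. A list fixed in advance whose median has the other sign at a common sum is named as such. The common sum was not run for the 4 lists added later.

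**Figure D2:**
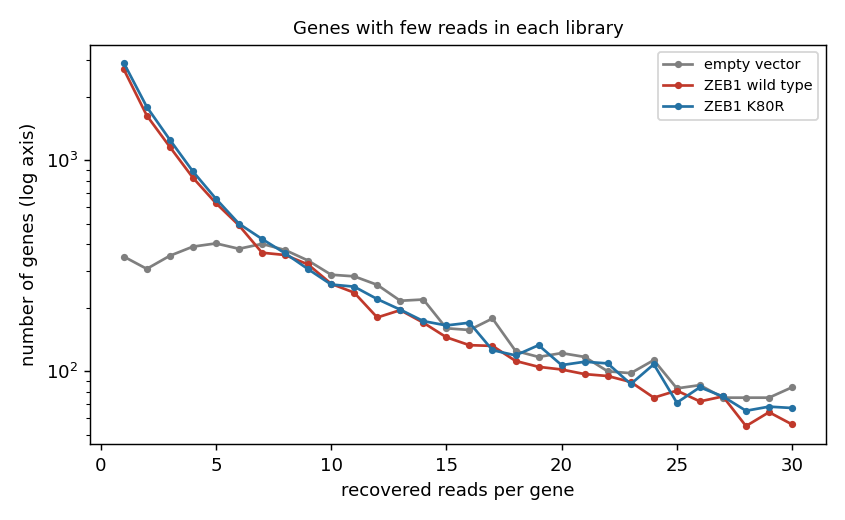
Number of genes, on a log axis, with 1 to 30 recovered reads in each library. The empty vector curve (grey) starts at 350 genes with 1 read, while the wild-type ZEB1 (red) and ZEB1 K80R (blue) curves start at 2705 and 2902.

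Against empty vector, the wild-type ZEB1 library held higher levels of NF-κB pathway genes, cytokines, hypoxia and glycolysis genes, mesenchymal genes and mitochondrially encoded mRNAs. CXCL8, which encodes the neutrophil chemokine interleukin-8 (ENSG00000169429; chromosome 4, 73740506 to 73743716), was at 179 against 9.05 FPKM, a ratio of 19.8 (17.7 to 22.2). TNFAIP3, a feedback inhibitor of NF-κB (ENSG00000118503; chromosome 6, 137867188 to 137883312), was at 31.8 against 2.41, a ratio of 13.2 (11.4 to 15.4). ICAM1, an adhesion receptor for leukocytes (ENSG00000090339; chromosome 19, 10270835 to 10286615), had 629 reads against 9. Heat shock genes had a median below the random range.

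Of 23 measured NF-κB components and feedback genes, 17 were at least 1.5-fold higher in the wild-type ZEB1 library than in the empty vector library, none was lower and 6 lay within that range. Their median difference of log2(FPKM + 1) was 1.33, where the central 95% of random lists of equal expression ran from −0.20 to 0.26. The inhibitor NFKBIA was at 69.6 against 15.9 and the superoxide dismutase SOD2 at 27.6 against 5.74. Of 16 measured pro-inflammatory cytokines and chemokines, 14 were higher and none lower, with a median of 1.87, or 1.19 among genes with a mean FPKM of at least 0.1. IL1A stood at 44.9 against 6.34, the monocyte chemokine CCL2 at 27.4 against 3.23 and CXCL3 at 13.4 against 1.14. No random list had a median as high as either of these lists. Members that passed the filter only through the wild-type library, such as ICAM1 at 12.3 against 0.153 FPKM, tilt these counts upwards.

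Hypoxia and glycolysis genes were higher in 15 of 28 cases and lower in none, with a median of 0.63. The glucose transporters SLC2A1, at 121 against 42.9 FPKM, and SLC2A3, at 47.5 against 15.1, and the aldolase ALDOC, at 42.0 against 13.0, were among them. Immediate early and AP-1 genes had 7 higher, 1 lower and 17 within range, with a median of 0.37 that was −0.07 at a common sum, still above the random range (percentile 99.43), and EGR1 stood at 7.58 against 1.18, JUNB at 65.3 against 18.8 and FOSL1 at 193 against 56.9. Genes of antigen presentation by MHC class I had 7 of 16 higher and none lower, with a median of 0.48, led by HLA-B at 12.2 against 3.40 and by TAPBP, which loads peptides onto class I molecules, at 63.5 against 29.2. Of 19 matrix protease and invasion genes, 9 were higher and none lower, with a median of 0.54, and the gelatinase MMP9 was at 29.7 against 2.13. Each of these medians lay above the central 95% of random lists.

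Among 31 measured mesenchymal genes, 12 were higher, 1 was lower and 18 lay within 1.5-fold, with a median of 0.52 against a random range of −0.16 to 0.28. The EMT transcription factor SNAI2 was at 10.6 against 3.02, the collagen COL6A2 at 46.6 against 17.9, the fibronectin receptor subunit ITGA5 at 132 against 55.6 and the hyaluronan receptor CD44 at 149 against 62.9. Of the 8 measured epithelial genes, 1 was lower and 7 lay within range, with a median of −0.00. The plakophilin PKP3 was the lower gene, at 2.79 against 5.15. Type I interferon response genes had 5 higher, 1 lower and 21 within range, with a median of 0.19 (−0.20 at a common sum), which lay inside the random range and above it after correction for transcript length and GC content (0.24, percentile 99.01), with lower or higher filters (percentiles 98.14 and 99.14) and by the mean of the list (99.81). IFITM3 was at 150 against 32.7 and IFITM1 at 6.91 against 0.816, the latter from 103 and 14 reads.

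All 13 mitochondrially encoded mRNAs were higher in the wild-type ZEB1 library than in the empty vector library, with a median of 2.77. MT-ATP6, an ATP synthase subunit, was at 10658 against 736 FPKM and MT-CYB, a subunit of complex III, at 4832 against 424. Heat shock genes had 4 of 13 lower and 1 higher, with a median of −0.39 against a random range of −0.24 to 0.43. The chaperones HSP90AA1, at 359 against 601, and HSPD1, at 144 against 256, were lower, and the co-chaperone BAG3 was higher at 74.5 against 46.9. Cell cycle genes had 6 of 34 lower and 2 higher, with a median of −0.19 at percentile 1.10, which moved inside the random range at a common sum (−0.62, percentile 2.74) and to −0.13 at percentile 8.39, inside the random range, after correction for transcript length and GC content. The replication helicase subunits MCM3, at 18.5 against 39.4, and MCM2, at 11.2 against 20.2, were lower, and the mitotic cyclin CCNB2 was higher at 18.0 against 9.78.

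The other lists had medians inside the random range, though TGF-β response genes lay above it by the mean of the list (percentile 99.81) and after the length and GC correction (98.24), and histones by the mean (98.92) and among genes with a mean FPKM of at least 0.1 (98.07). For TGF-β response genes 10 of 23 were higher and none lower (median 0.29, and −0.25 at a common sum), for Wnt targets 2 of 8 higher and none lower (0.23 and −0.15), and for p53 targets 3 of 25 higher and 3 lower (−0.10). Unfolded protein and integrated stress response genes had 7 of 31 higher and 2 lower (0.24, and −0.22 at a common sum), cholesterol synthesis 7 of 23 higher and 1 lower (0.23 and −0.22), and metallothionein and oxidative stress genes 4 of 18 higher and 2 lower (0.04 and −0.39). Cytosolic ribosomal protein genes had 16 of 42 higher and 1 lower (0.31, and −0.14 at a common sum), replication-dependent histones 4 of 10 higher and 1 lower (0.37 and −0.30), and housekeeping genes 6 of 24 higher and 3 lower (−0.02). Over the 12605 genes with a mean FPKM of at least 1, 690 were at least 2-fold higher and 477 at least 2-fold lower, and among the 10372 protein-coding ones these were 363 and 120. At a common sum the split was 1345 higher and 2936 lower among 17153 genes, and after correction for transcript length and GC content it was 561 and 596. The protein-coding genes with the largest deficits were BOLA2B, whose reads are shared with a near-identical copy and which is therefore uncertain, at 1.17 against 16.5 FPKM, the mitochondrial deformylase PDF, at 9.52 against 37.9, the complex I assembly factor NDUFAF8, at 29.8 against 108, and the mediator subunit MED18, at 10.4 against 38.6.

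Against empty vector, the ZEB1 K80R library had medians above the random range for mitochondrially encoded mRNAs and, by smaller amounts, for Wnt target, mesenchymal, TGF-β response and matrix protease genes, the last 3 with medians below 0 at a common sum and the first 2 above it (2.69 and 0.08). Of the 39 NF-κB genes and cytokines, 33 lay within 1.5-fold of the empty vector library, though the counting interval of the ratio excluded 1 for 24 of the 39. These intervals would be too narrow if several reads of the empty vector library came from the same molecule. Some of the 39 genes passed the filter only through the wild-type library and lay below an FPKM of 1 in both libraries compared here. Examples are ICAM1, at 0.344 against 0.153 FPKM, and CCL20, at 0.471 against 0.829. The pseudocount of 1 draws such genes within range, which raises the counts within range here and in the next paragraph. CXCL8 was at 12.5 against 9.05 FPKM, a ratio of 1.39 (1.19 to 1.61), TNFAIP3 at 2.93 against 2.41, a ratio of 1.22 (0.99 to 1.49), and ICAM1 had 17 reads against 9, a ratio of 2.25 (0.95 to 5.74).

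Of 23 NF-κB components and feedback genes, 20 lay within 1.5-fold, 1 was higher and 2 were lower in the K80R library, with a median of −0.10 at percentile 23.39 of random lists, which was 0.02 among genes with a mean FPKM of at least 5. The exceptions were CD83, at 6.09 against 3.65, the inhibitor NFKBIE, at 3.29 against 11.7, and SOD2, at 2.42 against 5.74. Of 16 cytokines and chemokines, 13 lay within range, with a median of 0.19 at percentile 89.77. This median lay above the random range with a pseudocount of 0.1 (0.43, percentile 99.07), among genes with a mean FPKM of at least 5 (0.41, percentile 98.44) and at a common sum, where it was −0.00 (percentile 98.69). CCL2, at 8.54 against 3.23, and the prostaglandin synthase PTGS2, at 1.37 against 0.275, were higher, and the growth factor CSF2 was lower, with 4 reads against 23.

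Mesenchymal genes had 9 of 31 higher, 2 lower and 20 within range, with a median of 0.23 against a random range of −0.23 to 0.19, −0.16 at a common sum, still above the random range (percentile 99.34), and 0.44 among genes with a mean FPKM of at least 5. CD44 was at 141 against 62.9, ITGA5 at 117 against 55.6 and fibronectin, FN1, at 117 against 57.4, and the tropomyosin TPM2 was lower at 45.1 against 114. Of the 8 epithelial genes, PKP3 was lower at 2.56 against 5.15 and 7 lay within range, with a median of 0.06 (−0.39 at a common sum). TGF-β response genes had 6 of 23 higher and 2 lower, with a median of 0.29 at percentile 99.32 and of −0.17 at percentile 97.92 at a common sum, and ID2, an inhibitor of basic helix-loop-helix factors, was at 2.31 against 0.228, from 68 and 8 reads. Wnt targets had 3 of 8 higher and none lower, with a median of 0.45 at percentile 98.91, and the Wnt effector TCF7L2 was at 6.96 against 3.44. Both calls ended among genes with a mean FPKM of at least 5, at percentiles 97.41 and 95.73. Matrix protease and invasion genes had 7 of 19 higher and none lower, with a median of 0.32 at percentile 98.61 and of −0.07 at percentile 99.59 at a common sum. The plasminogen activator PLAT was at 89.8 against 40.3, the collagenase MMP1 at 12.7 against 5.56 and the cathepsin CTSB at 123 against 64.9.

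All 13 mitochondrially encoded mRNAs were higher in the K80R library, with a median of 3.12, and MT-ATP6 stood at 12878 against 736 FPKM. Replication-dependent histones had 4 of 10 higher and 2 lower, with a median of 0.34 at percentile 98.04, a call that ended with a pseudocount of 0.1 (percentile 96.01), a lower filter (76.57), the mean of the list (96.12) or a common sum (median −0.04, percentile 94.84). HIST1H2BD was at 9.57 against 1.73. Type I interferon response genes had 5 of 27 higher and 1 lower, with a median of 0.06 inside the random range (−0.25 at a common sum), and IFITM3 stood at 107 against 32.7 and ISG15 at 7.98 against 23.6.

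The medians of the remaining lists lay inside the random range for K80R against empty vector, though MHC class I genes lay above it among genes with a mean FPKM of at least 0.1 (percentile 98.0) or 5 (97.53) and after the length and GC correction (97.7). MHC class I genes had 3 of 16 higher and 2 lower (0.25, and −0.17 at a common sum), p53 targets none of 25 higher and 4 lower (−0.05), cell cycle genes 2 of 34 higher and 2 lower (0.06 and −0.35), and unfolded protein and integrated stress response genes 4 of 31 higher and 6 lower (0.09 and −0.40). Hypoxia and glycolysis genes had 1 of 28 higher and 2 lower (−0.06), immediate early genes 3 of 25 higher and 3 lower (0.05, and −0.36 at a common sum), and cholesterol synthesis genes 5 of 23 higher and 3 lower (−0.05). Metallothionein and oxidative stress genes had 2 of 18 higher and 5 lower (−0.16), heat shock genes 1 of 13 higher and 3 lower (−0.26), ribosomal protein genes 6 of 42 higher and 9 lower (−0.08), and housekeeping genes 4 of 24 higher and 5 lower (−0.06). Genome-wide, 620 of 12605 genes were at least 2-fold higher and 561 at least 2-fold lower, with 239 and 231 among protein-coding genes. A common sum gave 1473 higher and 2890 lower, the length and GC correction 726 and 410, a mean FPKM of at least 5 gave 241 and 285, and a ratio of 1.5 gave 1592 and 1640. The largest deficits were those of NDUFAF8, at 19.97 against 108 FPKM, PDF, at 7.07 against 37.9, and the transmembrane protein gene TMEM160, at 8.61 against 44.1.

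Between the overexpression libraries, the K80R library had lower levels of NF-κB pathway genes and of pro-inflammatory cytokines than the wild-type library at a nearly equal level of ZEB1. Of the 39 genes of both lists, 30 were at least 1.5-fold lower in the K80R library, none was higher and 9 lay within that range, and the counting interval of the ratio excluded 1 for all 39. Some of these genes passed the filter on mean FPKM only through the wild-type library, which tilts these counts towards lower values in K80R. TNF, for example, stood at 0.075, 3.03 and 0.134 FPKM in the empty vector, wild-type and K80R libraries. CXCL8 was at 12.5 FPKM in the K80R library and 179 in the wild-type library, 14.3-fold lower (12.8 to 15.9). TNFAIP3 was 10.9-fold lower (9.40 to 12.6), SOD2 11.4-fold lower (10.4 to 12.5) and ICAM1 35.7-fold lower (22.1 to 61.7), the last from 17 and 629 reads.

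NF-κB components and feedback genes had 18 of 23 lower and none higher, with a median of −1.39 against a random range of −0.20 to 0.09. They included the subunits RELB, at 4.16 against 18.5, NFKB2, at 18.2 against 55.0, and NFKB1, at 8.51 against 15.4, the inhibitors NFKBIA, at 23.4 against 69.6, and NFKBIE, at 3.29 against 14.5, and the survival genes BIRC3, at 0.429 against 4.56, and TRAF1, at 1.30 against 8.75. TNFAIP2, TNFRSF9, TNIP1, IRF1, IER3, CD83, BCL3 and NUAK2 were also lower, by 1.97-fold for BCL3 to 6.89-fold for TNFRSF9. PLAU, RELA, NFKBIZ, RIPK2 and NFKBIB lay within 1.5-fold. Cytokines and chemokines had 12 of 16 lower and none higher, with a median of −1.68 against −0.20 to 0.14, or −1.06 among genes with a mean FPKM of at least 0.1. The interleukins IL1A, at 8.62 against 44.9, IL1B, at 42.5 against 111, and IL6, at 0.653 against 5.22, the chemokines CXCL3, at 1.62 against 13.4, and CCL20, at 0.471 against 3.27, and the growth factor CSF1, at 21.2 against 36.6, were among the lower genes. CSF2 had 4 reads in the K80R library and 153 in the wild-type library, TNF 3 and 70, and CCL5 5 and 69. IL32, at 0.725 against 5.69, and CCL2, at 8.54 against 27.4, completed the group, and LIF, IL11, PTGS2 and IL15 lay within range. None of 10000 random lists had a median as low as either list.

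**Figure D3:**
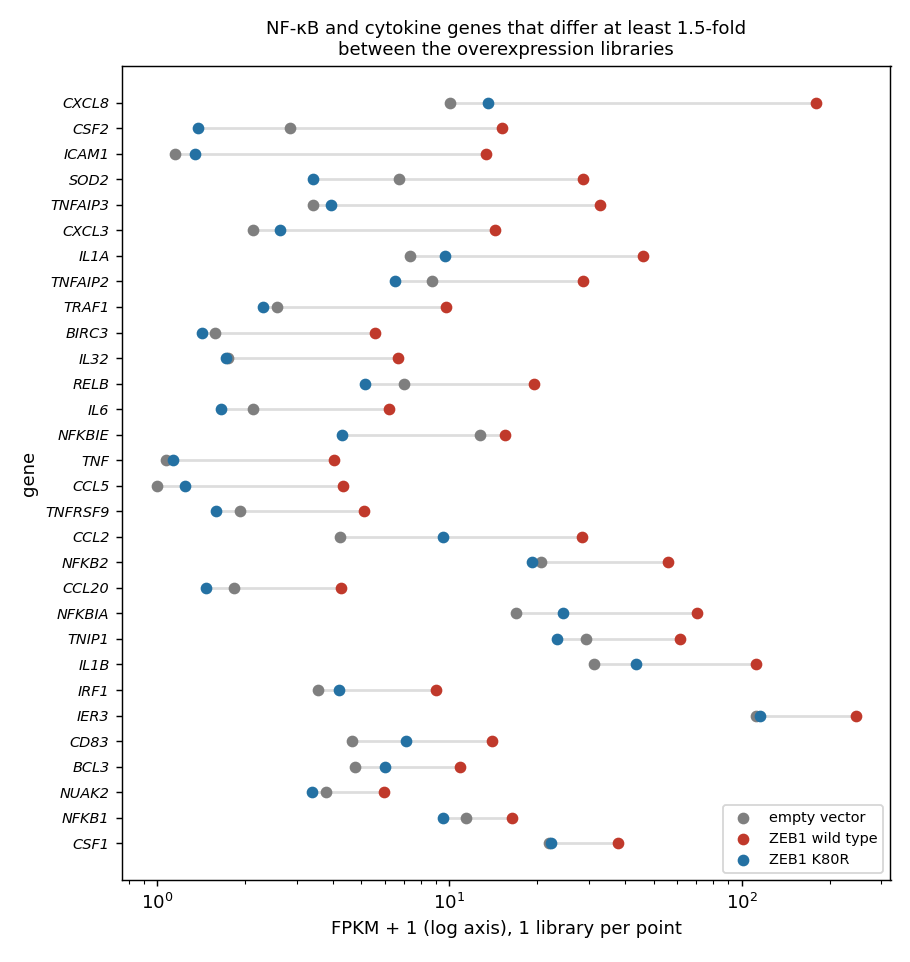
FPKM + 1, on a log axis, of the 30 NF-κB and cytokine genes that differ at least 1.5-fold between the overexpression libraries, with 1 point per library in grey for empty vector, red for wild-type ZEB1 and blue for ZEB1 K80R. The wild-type point is above the K80R point for all 30 genes, as for CXCL8 at 179 and 12.5 FPKM.

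Hypoxia and glycolysis genes were lower in the K80R library for 11 of 28 members and higher for none, with a median of −0.51 against a random range of −0.26 to 0.00. NDRG1 was at 72.9 against 198, the carbonic anhydrase CA9 at 4.41 against 13.0, ANKRD37 at 1.57 against 8.85 and the enolase ENO2 at 23.2 against 56.9. HILPDA, a hypoxia-induced lipid droplet gene outside the list, was at 4.86 against 29.9 and MMP9 at 4.98 against 29.7. Immediate early and AP-1 genes had 7 of 25 lower and 1 higher, with a median of −0.32 at percentile 0.21, and JUNB was at 23.3 against 65.3 and EGR1 at 2.54 against 7.58. MHC class I genes had 5 of 16 lower and none higher, with a median of −0.29 at percentile 0.85, with HLA-B at 4.92 against 12.2 and the immunoproteasome subunit PSMB9 at 3.03 against 6.98. Type I interferon response genes had 4 of 27 lower and 1 higher, with a median of −0.20 at percentile 0.34, and this call ended among genes with a mean FPKM of at least 0.1 (percentile 3.33) or 5 (percentile 3.54) and at a common sum (percentile 3.78). IFIH1, a sensor of viral RNA, was at 1.71 against 3.25, and SAMD9 was higher at 4.34 against 2.51.

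Mesenchymal genes mostly did not separate the overexpression libraries. Of 31, 27 lay within 1.5-fold, 3 were lower and 1 was higher in the K80R library, and the median of −0.17 lay inside the random range of −0.24 to 0.03. After correction for transcript length and GC content it was −0.16 at percentile 2.02, below the random range. The lower genes were the EMT transcription factors TWIST1, at 3.10 against 6.88, SNAI2, at 5.33 against 10.6, and SNAI1, at 3.12 against 5.93, and the collagen COL5A1 was higher at 23.7 against 14.7. CD44 and FN1 stood at 141 and 117 in the K80R library and 149 and 112 in the wild-type library. All 8 measured epithelial genes lay within range, with a median of −0.10, which was 0.22 at a common sum, 0.13 among genes with a mean FPKM of at least 0.1 and 0.03 after the length and GC correction.

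Cell cycle genes were slightly higher in the K80R library, with a median of 0.17 above the random range of −0.22 to 0.02, though 32 of 34 lay within 1.5-fold. MKI67, the proliferation marker Ki-67, was at 37.3 against 20.9, and the ubiquitin-conjugating enzyme UBE2C was lower at 49.97 against 78.9. All 13 heat shock genes lay within range, with a median of 0.14 at percentile 99.63, and HSPA8 was at 433 against 322. All 8 Wnt targets also lay within range, with a median of 0.25 at percentile 99.47, a call that ended among genes with a mean FPKM of at least 5 (97.14). Of the 13 mitochondrially encoded mRNAs, 1 was higher, MT-ND5 at 2276 against 1452, and 12 lay within range, with a median of 0.30 above the random range of −0.43 to −0.03, which was 0.58 after the length and GC correction. Ribosomal protein genes had 2 of 42 lower, with a median of −0.48 against −0.34 to −0.10, and RPL13 was at 99.6 against 157 and RPS6 at 246 against 370. Unfolded protein and integrated stress response genes had 2 of 31 lower and none higher, with a median of −0.27 at percentile 0.54 (−0.16 after the length and GC correction), and the lower genes were CEBPB, at 31.4 against 65.9, and DDIT4, at 7.41 against 15.8. Metallothionein and oxidative stress genes had 4 of 18 lower and none higher, with a median of −0.27 at percentile 1.08 that moved inside the random range after the length and GC correction (−0.10, percentile 18.14) or among genes with a mean FPKM of at least 5 (percentile 9.96). MT2A, a metal-binding protein gene, was at 267 against 464.

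Inside the random range for K80R against wild type lay the TGF-β response genes, with 1 of 23 higher and 4 lower (−0.02), and the matrix protease genes, with none of 19 higher and 3 lower (−0.14). So did the p53 targets, with none of 25 higher and 2 lower (−0.19), the cholesterol synthesis genes, with all 23 within range (−0.19), the histones, with 1 of 10 higher and 2 lower (−0.24, and 0.05 after the length and GC correction), and the housekeeping genes, with 1 of 24 higher and 2 lower (−0.13). Genome-wide, 207 of 12605 genes were at least 2-fold higher and 144 at least 2-fold lower in the K80R library, but among protein-coding genes 10 were higher and 68 lower. The length and GC correction gave 422 and 82, a mean FPKM of at least 5 gave 38 and 58, and a ratio of 1.5 gave 557 and 653. Across genes, the difference was higher for longer transcripts (Spearman's rho 0.45 over 10352 genes, which are not independent replicates), with a median of −0.26 among transcripts of up to 2157 bases and of 0.14 among those from 5963 bases. It was lower for transcripts with a higher GC content (rho −0.32). The largest excess among protein-coding genes was that of GAGE12J, a member of a multicopy family and therefore uncertain, with 34 reads against 0, and FAM111B, a gene linked to DNA replication, was at 4.18 against 1.43 FPKM.

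**Figure D4:**
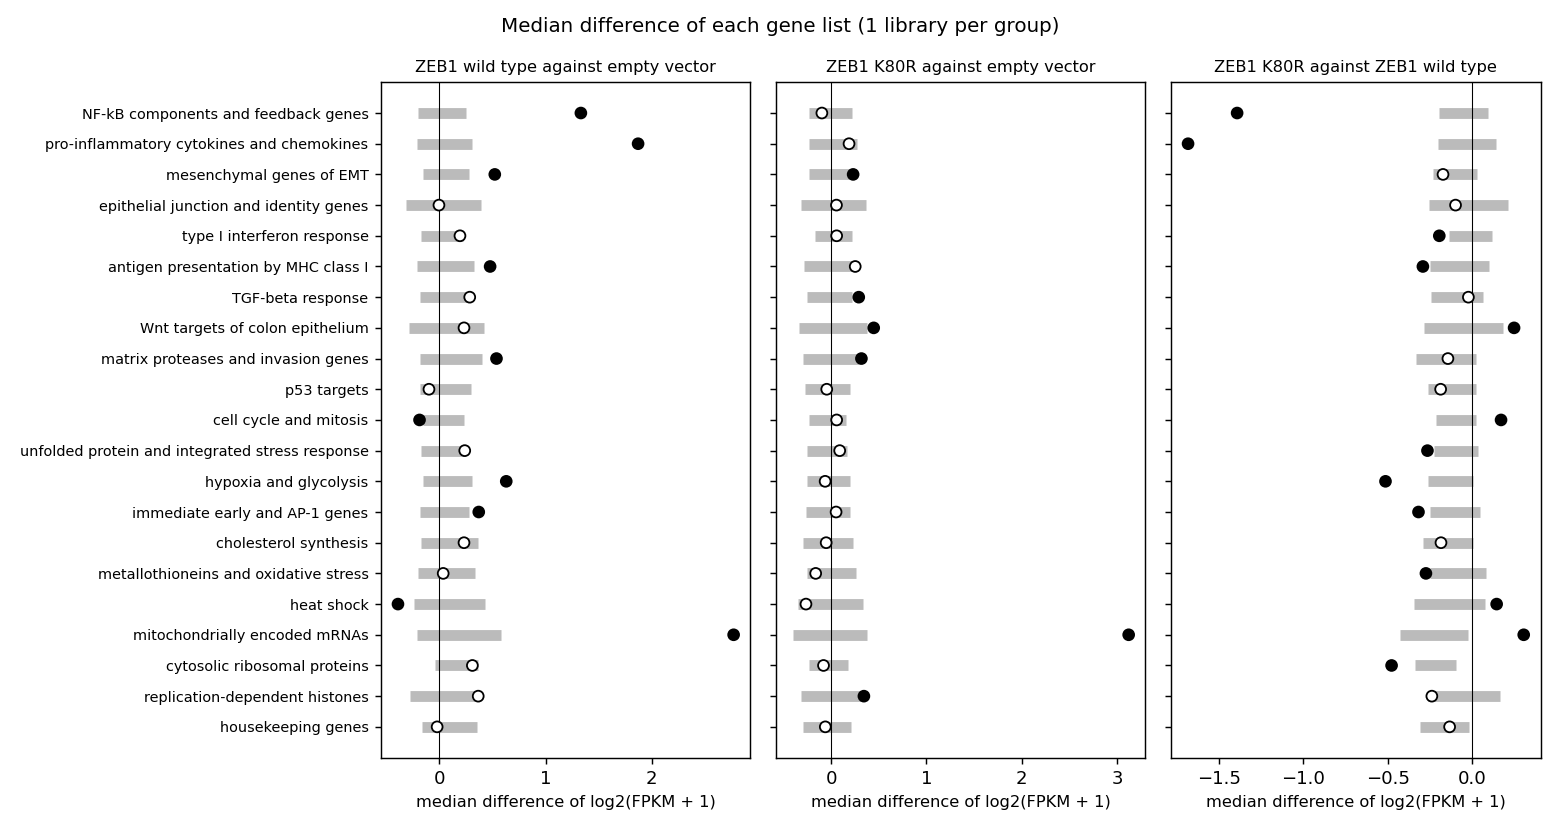
Median difference of log2(FPKM + 1) of each of 21 gene lists in the 3 comparisons, with grey bars for the central 95% of 10000 random lists of equal size and expression, and filled points for medians outside that range. The NF-κB list lies at 1.33 for wild type against empty vector, −0.10 for K80R against empty vector and −1.39 for K80R against wild type.

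The differences of both overexpression libraries from the empty vector library overlapped. Of the genes at least 2-fold higher, 411 were shared between the 690 of wild type and the 620 of K80R, and of those lower, 300 were shared between 477 and 561. Independent lists of these sizes would share 33.9 and 21.2 genes. Unchanged libraries simulated against the shared empty vector library shared on average 18.9 higher and 9.0 lower genes over 100 simulations with counting error alone, and 137.8 and 97.4 when each molecule of the empty vector library gave 5 reads. The simulations hold no difference between cultures or preparations, and the single control library could not be split. Some or all of the excess may therefore come from that library. Among the shared genes were all 13 mitochondrially encoded mRNAs, NDUFAF8, PDF and MED18.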

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

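At a common sum of FPKM (TPM), medians that lay above the random range lay below 0 for the immediate early and AP-1 list in wild type against empty vector (−0.065) and for the mesenchymal (−0.157), TGF-β response (−0.166), matrix protease (−0.066) and histone (−0.037) lists in K80R against empty vector. This scaling shifts the median gene by −0.45 and −0.43 in these comparisons, and all these lists but the histones stayed above the random range. No other median outside the random range changed sign under an alternative run for it. For named genes only the pseudocount of 0.1 and the median ratio rescaling were compared, and under these no gene whose counting interval excludes 1 changed sign. The common sum was not run for named genes. Small differences can change sign after the length and GC correction. FN1 for K80R against wild type, at a ratio of 1.05 (1.03 to 1.07), went from 0.073 to −0.14 on the log2 scale. Medians inside the random range changed sign in 32 of 243 pairs of list and alternative, 16 of them at a common sum. Which direction held more genes also varied: lower genes outnumbered higher ones at a common sum in both comparisons with empty vector, after the length and GC correction for wild type against empty vector (561 higher, 596 lower), with a mean FPKM of at least 5 (241, 285) or a ratio of 1.5 (1592, 1640) for K80R against empty vector, and among protein-coding genes (10, 68), with a mean FPKM of at least 5 (38, 58) or a ratio of 1.5 (557, 653) for K80R against wild type. The common sum for lists, the length and GC correction, the filter without the empty vector library and the restriction by counting interval were chosen after the data were seen. No paired analysis was possible because each group has 1 library. The number of genes at least 2-fold different, which was 1167 for wild type and 1181 for K80R against empty vector and 351 for K80R against wild type, became 1814, 1859 and 698 with a pseudocount of 0.1, 501, 526 and 96 with a mean FPKM of at least 5, 4281, 4363 and 1453 at a common sum, 483, 470 and 78 among protein-coding genes and 3186, 3232 and 1210 at a ratio of 1.5. Without a filter it was 1781 for K80R against empty vector and 673 for K80R against wild type. Stricter filters and protein-coding genes leave fewer genes to count and the ratio of 1.5 admits more, and the common sum raises the number of genes past the filter from 12605 to 17153. The shared genes against empty vector, 711, became 1176 with a pseudocount of 0.1, 286 with a mean FPKM of at least 5 and 2065 at a ratio of 1.5. ZEB1 at a common sum stood at 25.289, 31.961 and 33.949 in the empty vector, wild-type and K80R libraries, in the same order as the deposited values. The median ratio rescaling, the length and GC correction and the restriction by counting interval kept each count within 1.5 times, at 1159, 1157 and 1056 for wild type against empty vector, 1180, 1136 and 1061 for K80R against empty vector, and 352, 504 and 242 for K80R against wild type, and the filter without the empty vector library gave 400 for the last. The median ratio rescaling shifts the median gene by only −0.011, 0.009 and 0.02, so the similar counts under it say little about other scalings. Of 21 lists, 10, 6 and 13 lay outside the random range in the 3 comparisons, and these counts stayed within 1.5 times under every alternative. The NF-κB and cytokine lists stayed outside it, on the same side, for wild type against empty vector and for K80R against wild type under all alternatives run. Of 209 named gene differences, 28 moved beyond their counting interval with a pseudocount of 0.1 and 4 with the median ratio rescaling. The cause of the lost and gained list calls given in the report was not tested. Depth limits the genes with few reads, such as CSF2 with 4 reads and TNF with 3 reads in the K80R library, whose ratios have wide intervals.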

Other observations

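Of the tests below, those on the nuclear-encoded respiratory chain, on the intestinal genes not looked at before, and on transcript length and GC content for the mitochondrially encoded mRNAs and the NF-κB genes were set before their results were seen. The tests of housekeeping genes at 0 reads, of the colon epithelial genes in the empty vector library, of low read counts, of counting error, of scaling, of the DNA replication genes and of replication by further cultures were chosen after the results were seen.

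DNA replication and damage response genes were higher in the ZEB1 K80R library than in the wild-type ZEB1 library. The list was drawn up after genes of this kind had been noticed, and 7 genes seen by then were left out of it. Of its 32 measured genes, 7 were at least 1.5-fold higher, none was lower and 25 lay within range, with a median of 0.38 against a random range of −0.12 to 0.13. MCM10, which loads replication polymerases, was at 6.07 against 3.28 FPKM, the origin recognition subunit ORC6 at 5.14 against 2.94, and the repair genes BRCA1 and BRIP1 at 3.78 against 2.15 and 1.85 against 0.853. Against empty vector the same list was lower in the wild-type library, with 9 lower, 1 higher and a median of −0.39, and had a median of 0.01 in the K80R library. A trend with transcript length and GC content predicts that the median returns to the random range after the correction, and it stayed at 0.368.

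As a set, nuclear-encoded subunits of the respiratory chain did not follow the mitochondrially encoded ones. Had they moved together, the median of the 73 measured subunits would have lain above the random range in both overexpression libraries. It was −0.00 for wild type against empty vector, with 16 higher and 9 lower, and −0.13 at percentile 2.5, the edge of the random range, after correction for length and GC content. It was −0.356 for K80R against empty vector, with 11 higher and 22 lower, below the random range of −0.17 to 0.09 and still −0.26 after the correction. For K80R against wild type it was −0.34, and −0.19 after the correction. COX6C was at 55.3, 21.2 and 14.1 FPKM and COX8A at 53.01, 168 and 124 in empty vector, wild type and K80R.

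The near absence of colon epithelial transcripts from all 3 libraries labelled HCT116 was weighed first. Estimates that failed across a library would also put common genes at 0, and 0 of 66 housekeeping and ribosomal protein genes had 0 reads in any library. A failure confined to particular genes would not show in this count. Repression by the introduced ZEB1 was argued against as the whole cause by the 45 epithelial genes. That list was fixed in advance, but no outcome was set in advance for it. In the empty vector library, made without the introduced ZEB1, 10 of them reached an FPKM of 1 and 25 had 0 reads. Only 10 had 0 reads in all 3 libraries, and low genes drop out of the empty vector library more often, as given below. The 25 may therefore overstate absence. In that library, 0 of the 19 colon epithelial genes reached an FPKM of 1, but this count adds no support, since these genes were chosen after their values had been seen. Cells other than the labelled line may be the source. In a list of 35 intestinal epithelial genes not looked at before, 9 had a mean FPKM of at least 1. These included KLF5 at 11.01, 7.07 and 8.37, FERMT1 at 5.49, 4.396 and 6.35 and GATA6 at 2.28, 3.33 and 2.78. All others lay below an FPKM of 1 in every library, and 6, among them AGR2 and USH1C, had 0 reads throughout. The share of 9 in 35 lay just above the bound set in advance for absence and below that for presence, so this test did not decide. A changed state of the labelled line, shared by all 3 libraries, was not tested, and genotyping of the cultures would decide between them.

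The distance of the empty vector library from both others was weighed next. Fewer distinct molecules behind its reads predicts that lowly expressed genes drop out of it, and among 8745 genes with 1 to 10 reads in the wild-type library the share at 0 reads was 2.13 times as high in the empty vector library as in the K80R library, 62.1% against 29.2%, at mean reads of 4.14 and 3.88. This is consistent with a less complex empty vector library, a hypothesis found and tested on the same counts. A trend with length and GC content as the cause of the high mitochondrially encoded mRNAs was argued against, since their median for wild type against empty vector was 2.65 after the correction. An effect of the introduced ZEB1 on these mRNAs cannot be told apart from a property of the library or culture, since the series holds 1 empty vector library.

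The lower NF-κB and cytokine genes in the K80R than in the wild-type library do not involve the empty vector library. Counting error was argued against, since the interval excluded a ratio of 1 for 100% of the 39 measured genes of both lists. Some of these genes passed the filter only through the wild-type library. Scaling was argued against by the housekeeping genes, whose median was −0.135, and a trend with length and GC content by the median of the NF-κB list after the correction, −1.264, below all random lists. An effect of the K80R change is a candidate explanation, and it cannot be told apart from a difference between the cultures, such as density or time since the last medium change, since each line has 1 library. Hypoxia and glycolysis genes differed in the same direction, with a median of −0.51. At least 3 further cultures per line would show whether the difference repeats between cultures. They would not tell the K80R change apart from a lasting difference between the lines.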
